A study of Arabidopsis thaliana with 6 samples.

How the data were processed

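Leaves of Col-0 and of the mutant prors1-2 were profiled on 3 Affymetrix arrays each, 1 sample per array. Per the labels' protocols, RNA was purified on silica columns and biotinylated cRNA was made from total RNA by the manufacturer's procedure. The deposited table holds log2 values, 1 per probe set and array, made with GCRMA per the submitters' processing notes; the version and the probe-set definition are not given in the sources used here. GCRMA subtracts a sequence-dependent background, equalises the distribution of the arrays and summarises the probes of each set, so a change shared by most transcripts is removed and dim values are compressed towards a floor. Values were taken as deposited. Their range and medians were checked, and no 2 arrays held the same values.

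Each array was placed in its group by its title. The labels number the replicates 1 to 3 in both groups and do not say that they came from separate plants or pools, so p-values measure the spread between these samples, which may be technical. No batch or scan date was in the labels. Col-0 was 4 weeks old and prors1-2 was 38 days old, and age could not enter the model because it changed with genotype.

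Of 22810 probe sets, 64 controls were left out and 22746 were tested. The platform annotation paired 13513 with exactly 1 gene and 503 with several, and 8730 carried no name here. Gene names were updated through gene identifiers in RefSeq's table for assembly TAIR10.1, which held 13436 of the single-gene probe sets; 23 were placed by an organelle symbol and 54 kept the annotation's name. No probe set paired with PRORS1 (AT5G52520), so its transcript was not analysed here and could not check the labels. No coordinates are printed, as the build behind the annotation is not given in the sources used here.

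Differences were tested with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Positive differences mean higher in prors1-2, and SE is the moderated standard error. Data were simulated with the same levels and limma's moderated variances, each value drawn independently, with 200 of 22746 probe sets changed. The test recovered 94% of 2-fold and 100% of 4-fold changes, and 5.83% of its calls were unchanged probe sets. The simulation held no effect shared by the probe sets of an array, so recovery in the real data may be lower. Of 200 simulated unchanged lists of 10 genes, 3% had a camera p under 0.05, in data whose genes were drawn independently.

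Gene lists for organelles, photosynthesis, stress, hormones, development and cell-type markers were fixed before the data were examined. A list was tested with camera at a preset correlation of 0.01 when at least 4 of its genes were measured, with the brightest single-gene probe set of each of 13356 genes. Of 36 fixed lists, 11 were tested, 19 had 1 to 3 measured genes and 6 had none and were not analysed here; those are sigma factors and retrograde regulators, nitrogen assimilation, the morning clock, cytosolic heat shock, floral organs and vascular tissue. A fixed list of cytosolic ribosomal proteins that relied on gene descriptions was void, because the tables used here hold none, and was replaced by loci. That list, further thylakoid and respiratory chain loci, pooled photosynthesis genes and families sharing a symbol stem were added after the annotation was seen and before the groups were compared. The PPR list of 458 loci and the division of plastid genes were written after values were seen. The PPR loci came from general knowledge of the family, and the tables used here hold no descriptions against which each could be checked. No call of the fixed lists held with an estimated correlation after adjustment over the lists.

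Genes were named by a rule fixed before the data were examined: PRORS1; the 10 largest rises and 10 largest falls among single-gene probe sets not shared between transcripts, with an adjusted p under 0.05, at least 2-fold, a brighter group mean of at least 6 and no overlap between the groups; and in each list up to 2 rises and 2 falls past the test with a brighter group mean of at least 4, or, where none passed, the member with the smallest p at any level. The last part gave 20 of the 49 named genes, which the text summarises together.

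Alternatives were no trend, a robust prior, leaving out dim probe sets (brighter group mean under 4), a second quantile normalization, median centring, replicate number as a block, array weights, each array left out, 1 probe set per gene, leaving out shared probe sets, a 2-fold minimum, and for lists an estimated correlation, ranks and fry. Scaling to the poly(A) spikes and a covariate from the 3' and 5' control probe sets were added after the data were seen. Control values were compared with exact permutation tests.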

Results

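Transcript levels were measured in leaves of Arabidopsis thaliana with 6 single-colour Affymetrix arrays, 3 of the wild-type accession Col-0 and 3 of prors1-2. The prors1-2 line is a mutant of PRORS1, the gene of the prolyl-tRNA synthetase that charges tRNA for protein synthesis in plastids and mitochondria. Plants grew on soil in long days, and the submitters describe the leaves as being of one developmental stage although Col-0 was 4 weeks old and prors1-2 was 38 days old, so genotype and age in days changed together in every comparison. The array medians lay between 5.96 and 6.07 on the log2 scale, and the number of arrays limits the precision of the values. Across probe sets, which are not independent replicates, the mean correlation of an array was 0.989 to 0.992 with its own group and 0.982 to 0.987 with the other group. The comparison asks which transcripts of the nucleus and of the organelles differ between Col-0 leaves and leaves of a line mutated in this synthetase gene; organellar protein synthesis was not measured.

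Leaves of prors1-2 had higher levels of many pentatricopeptide repeat (PPR) transcripts and of 3 of 7 measured markers of mitochondrial dysfunction. Higher levels were also seen for 8 of 15 plastid-encoded ribosomal protein genes and 2 of 4 plastid RNA polymerase genes. Some transcripts of cell wall expansins and of plastid-encoded photosystem II subunits were among those that fell most. Whether poly(A) priming differed between plastid genes was not tested. Between Col-0 and prors1-2, 1121 of 22746 probe sets differed, of which 809 were higher and 312 lower in prors1-2. A change of at least 2-fold was seen for 374 probe sets, with 277 higher and 97 lower. The orphan gene QQS rose most among the named genes, from 7.48 ± 0.60 to 10.70 ± 0.17 (log2, SD, n = 3 per group), a 9.30-fold difference. The expansin gene EXPB1 fell by 2.40 on the log2 scale, from 7.54 ± 0.33 to 5.13 ± 0.43. These calls used limma's moderated test with Benjamini-Hochberg adjustment over all probe sets and an adjusted p under 0.05. The count dropped to 337 without Col-0 replicate 1, 557 without Col-0 replicate 2, 693 without Col-0 replicate 3, 547 without prors1-2 replicate 1 and 513 without prors1-2 replicate 2. Levels are relative to the whole array, and centring each array on its own median changed the split to 666 higher and 439 lower. Scaled to the poly(A) spike controls, the median of all genes was -0.63 and 202 probe sets were higher and 16080 lower, so rises and falls are given relative to the other transcripts and list medians between 0 and 0.61 turn negative on that scale.

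**Figure D1:**
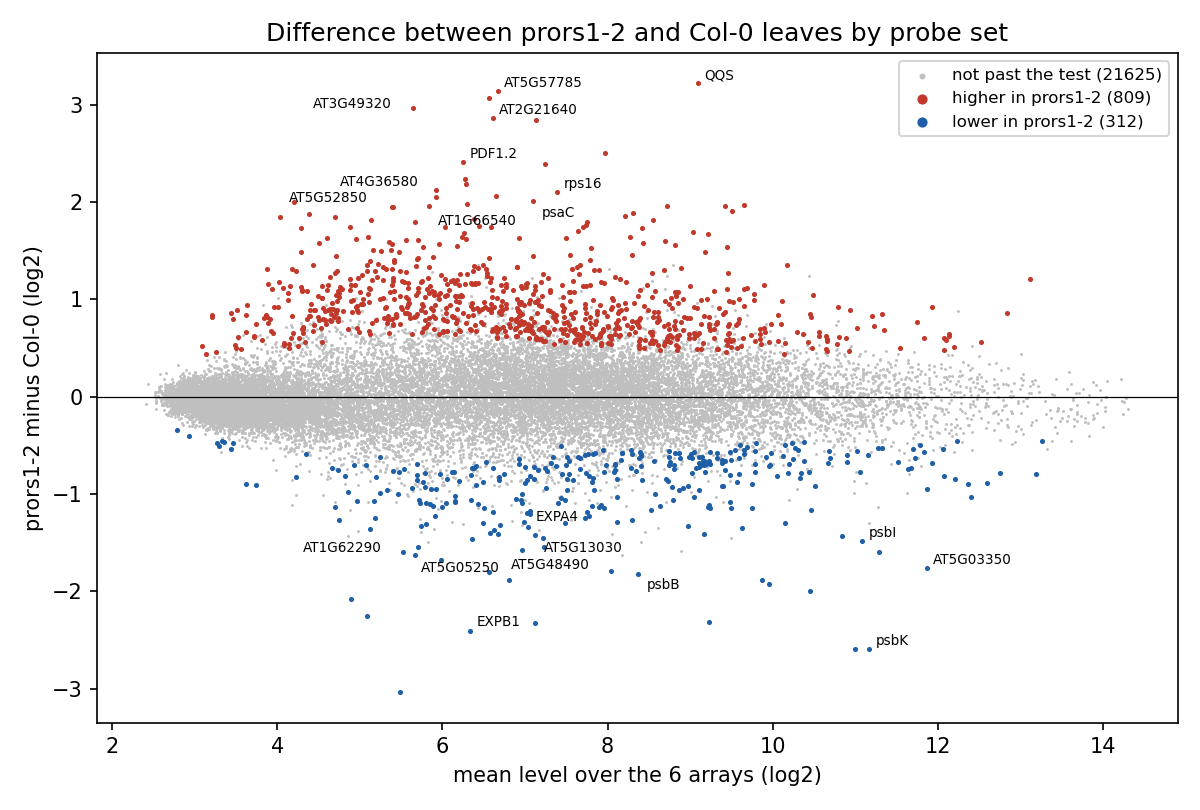
Each point is a probe set, with its mean level over the 6 arrays on the horizontal axis and the difference prors1-2 minus Col-0 on the vertical axis, both in log2 units; red and blue points passed an adjusted p under 0.05. The 809 higher probe sets outnumber the 312 lower ones, and labels mark the 10 largest rises and 10 largest falls taken by the rule for named genes.

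Only 627 of the 1121 changed probe sets were paired with exactly 1 gene, and the others could not enter the rankings of rises and falls. Among the 10 largest rises so ranked, 7 besides QQS were nuclear genes and 2 were plastid genes. AT5G57785 rose by 3.14 ± 0.33 (log2, SE, n = 3 per group) and AT3G49320 by 2.97 ± 0.24. AT2G21640, known as UPOX for its induction by oxidative stress, rose by 2.86 ± 0.38, with an adjusted p of 0.00406 in limma. The plant defensin gene PDF1.2, a marker of jasmonate and ethylene signalling, rose 5.31-fold with an adjusted p of 0.00549. AT4G36580 rose by 2.05 ± 0.18, the cytochrome P450 gene AT1G66540 by 1.96 ± 0.16 and the PPR gene AT5G52850 by 1.95 ± 0.19. The plastid genes rps16 and psaC completed the group with 4.29-fold and 4.03-fold rises. All 10 passed the test with any single array left out.

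The 10 largest falls held 3 plastid genes of photosystem II, psbK, psbB and psbI, and the expansin genes EXPB1 and EXPA4, whose products loosen cell walls during growth. EXPA4 fell by 1.34 on the log2 scale with an SE of 0.27. The lectin-like gene AT5G03350 was abundant in Col-0 at 12.75 ± 0.49 and reached 10.99 ± 0.36 in prors1-2 (log2, SD, n = 3 per group). AT5G48490, a relative of the lipid transfer protein DIR1, fell by 1.79, the aspartic protease gene AT1G62290 fell by 1.60, AT5G05250 fell by 1.63 and AT5G13030 fell by 1.42 on the log2 scale. The calls on EXPA4, AT5G05250, AT5G13030, psbK and psbI were lost when some single arrays were left out, with highest adjusted p values over the alternatives of 0.0698, 0.0655, 0.0875, 0.119 and 0.117 in limma.

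Of 69 plastid-encoded genes measured, whose median difference was 0.15, or -0.46 when scaled to the poly(A) spikes, 20 rose, 6 fell and 43 did not pass the test; adjusted over the list alone, 24 rose and 11 fell. With each of the 6 arrays left out in turn 8 to 13 rose and 1 to 7 fell, and scaled to the poly(A) spikes 6 were higher and 31 lower. With the 3' to 5' signal of the control probe sets as a covariate, 0 probe sets passed in limma, plastid ones included. Gene-specific differences in RNA processing or in poly(A) priming were not tested, and they bear on every plastid value here. Housekeeping genes, which here are those of the plastid's ribosomal proteins and RNA polymerase, the splicing factor matK, the protease subunit clpP and accD of fatty acid synthesis, rose for 12 of 22 and fell for 0 in limma, with 14 higher and 1 lower at an unadjusted p under 0.05. The lower one was rps14, at -0.70 on the log2 scale with an adjusted p of 0.0576 and no overlap between the groups. The 12 and 0 became 6 and 0 without Col-0 replicate 1, 8 and 0 without prors1-2 replicate 1, 7 and 1 without prors1-2 replicate 3, and 4 higher and 3 lower when scaled to the poly(A) spikes. Besides rps16, rpl20 rose 3.52-fold and rps4 2.32-fold, and the polymerase genes rpoC1 and rpoC2 rose 2.00-fold and 2.14-fold, whereas rpoA and rpoB did not pass, with adjusted p values of 0.661 and 0.810. Of 43 photosynthesis genes, 7 rose and 6 fell. These counts became 1 to 4 and 1 to 6 with each of the 6 arrays left out in turn, the lowest being 1 and 1 without Col-0 replicate 1. They were 1 higher and 25 lower when scaled to the poly(A) spikes. As deposited, the falling ones were psbK, psbB, psbI, psbD and psbT of photosystem II and ndhJ of the NDH complex. Of 15 psb genes 5 thus fell and 8 did not pass, while psbN rose by 0.81 and psbZ by 0.51 on the log2 scale. The sign of psbZ turns when scaled to the poly(A) spikes. The other rising ones included psaC of photosystem I and rbcL, the large subunit of Rubisco, at 1.80-fold. The mean difference was 0.65 over the housekeeping genes and -0.13 over the photosynthesis genes, a gap of 0.78 on the log2 scale. This gap had p = 0.00024 in a two-sided permutation test over genes. The genes are not independent, because they share operons and were read on the same 6 arrays. That p therefore does not measure the spread between samples. Over the arrays the photosynthesis mean overlapped between the groups, with an exact permutation p of 0.7, and its difference was 0.02 without prors1-2 replicate 1 and -0.27 without prors1-2 replicate 3, so no direction is given for it. The housekeeping mean was higher in prors1-2 without overlap, with an exact permutation p of 0.1, and its difference was 0.04 when scaled to the poly(A) spikes. Without clpP and accD, 11 of 20 rose, and the gap was 0.79 on the log2 scale with p = 3e-04 in the same permutation test over genes. This split of the list, and leaving out clpP and accD, were chosen after the values were seen. As a whole the list passed limma's camera set test with an adjusted p of 0.00832 and an upward direction, and the adjusted p was 0.703 with an estimated correlation between genes. The call on the list was also lost without Col-0 replicate 3 (adjusted p = 0.0582 in camera), without prors1-2 replicate 3 (adjusted p = 0.129 in camera) and without dim probe sets (adjusted p = 0.056 in camera). With the 3' to 5' covariate the call on the list held, with an adjusted p of 0.000105 in camera at the preset correlation. In limma's fry, which tests a list against no change rather than against the other genes, the adjusted p was 0.395.

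**Figure D2:**
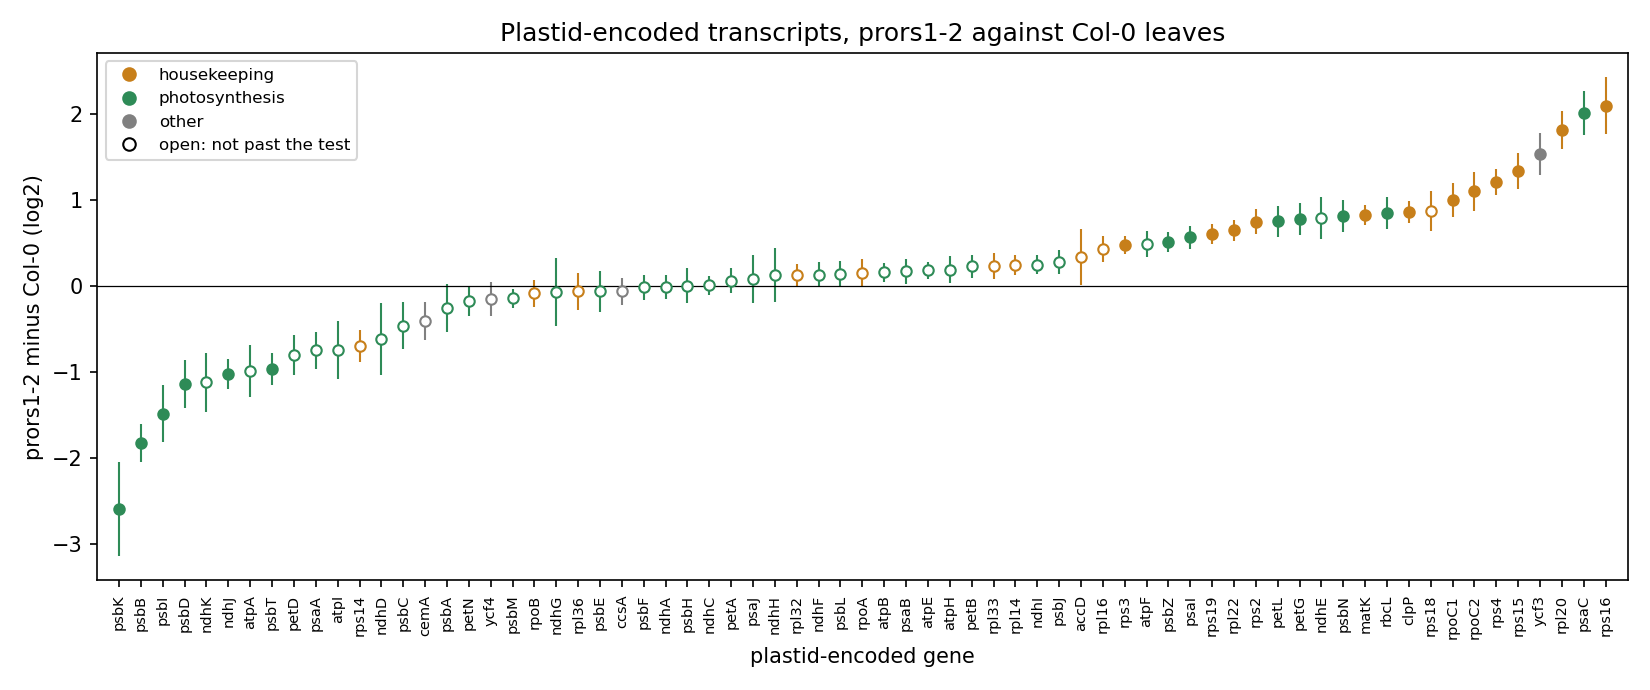
Each point is a plastid-encoded gene, ordered by its difference prors1-2 minus Col-0 (log2, bars are the SE from limma, n = 3 per group) and coloured by class; filled points passed an adjusted p under 0.05. The left end holds psbK, psbB, psbI and psbD, and the right end holds rps16, psaC, rpl20 and ycf3, all relative to the array-wide level: scaled to the poly(A) spikes every difference would be 0.61 lower.

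PPR proteins bind organellar RNA and act in its splicing, editing and stability, and most are encoded in the nucleus and imported into plastids or mitochondria. The membership of the PPR list could not be checked, because the tables used here hold no gene descriptions. Of 312 measured PPR genes, 104 rose, 0 fell and 208 did not pass limma's test, so that 33.3% of PPR genes rose against 2.84% of the other genes. At an unadjusted p under 0.05, 186 were higher and 1 lower. The mean over the PPR genes was 5.09 ± 0.03 in Col-0 and 5.61 ± 0.08 in prors1-2 (log2, SD, n = 3 per group), with no overlap between the arrays, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Of the 312, 287 had a positive difference, and the median was 0.45. Large rises included AT5G39350 at 3.38-fold and OTP81, a factor of plastid RNA editing, at 2.71-fold. The list was written after several PPR genes had been seen among the largest rises, and these examples were chosen after their values were seen; without the 7 members seen beforehand the median of the other 305 was 0.43. In camera the list had an adjusted p of 3.18e-38 with the preset correlation, against 0.233 with an estimated correlation, both over 37 lists. The poly(A) spike controls were 0.61 higher in prors1-2, and scaled to them 30 PPR genes were higher and 54 lower, and the PPR median was -0.16 where the median of all genes was -0.63, so the rise is relative to the other transcripts on the array. The count of risen genes was 37 without Col-0 replicate 1, 55 without Col-0 replicate 2, 56 without prors1-2 replicate 1 and 60 without prors1-2 replicate 2. It was 34 with the replicate number as a block and 0 in limma with the 3' to 5' signal of the control probe sets as a covariate, where the median was 0.42; the actin part of that signal was higher in prors1-2 without overlap between the groups.

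Among 7 measured of 20 listed genes of the mitochondrial dysfunction response, 3 rose, 0 fell and 4 did not pass the test. AOX1A of this list was not measured. By sign alone, 4 differences were positive and 3 negative. Adjusted over the list alone, 4 rose and 1 fell. The fall was NDB2, named after its values were seen, at -0.64 on the log2 scale without overlap between the groups. Its adjusted p in limma was 0.0333 over the list alone and 0.1665 over all probe sets. AT2G21640 is described above, and AT5G51440, which encodes a small heat shock protein of mitochondria, rose to 5.21 ± 0.38 (log2, SD, n = 3 per group) with an adjusted p of 0.00133 in limma. AT2G04050, a transporter gene of the MATE family, was named after its values were seen and rose to 4.87 ± 0.57 with an adjusted p of 0.0178. No fold is given for these 2 genes, because their Col-0 means lie under 4 on the log2 scale, where GCRMA compresses differences. The list passed camera with an adjusted p of 0.00988, against an adjusted p of 0.208 with an estimated correlation, and on ranks the adjusted p was 0.217. Of 10 measured nuclear genes of the mitochondrial respiratory chain, 2 fell and 8 did not pass, and adjusted over the list alone 3 fell. AT3G15640, a subunit of cytochrome c oxidase, fell by 0.58 on the log2 scale, and AT3G27240, cytochrome c1, fell by 0.55. The list passed camera downwards with an adjusted p of 0.00832, against 0.208 with an estimated correlation and 0.0508 with the 3' to 5' covariate. A further 31 respiratory chain genes, listed by locus before the groups were compared, held 0 genes past the test in limma, with 2 higher and 3 lower at an unadjusted p under 0.05, and had a median of 0.01, with a camera p of 0.628. The calls on AT3G15640 and AT3G27240 were each lost with 5 of the 6 arrays left out in turn, with adjusted p values up to 0.135 and 0.164 in limma.

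Of 16 mitochondrion-encoded genes, ccb382, a gene of cytochrome c maturation, rose by 1.07 ± 0.12 (log2, SE, n = 3 per group) and the other 15 did not pass. Among 4 organellar tRNA synthetase genes other than PRORS1, the aspartyl-tRNA synthetase gene AT4G33760 rose by 1.02 ± 0.18 (log2, SE, n = 3 per group), and 3 did not pass. The call on AT4G33760 was lost with 2 of the 6 arrays left out, with adjusted p values up to 0.0684 in limma. The synthetase list had an adjusted p of 0.0208 in camera, against 0.703 with an estimated correlation. It was lost without Col-0 replicate 1 (adjusted p = 0.0568 in camera), without prors1-2 replicate 1 (adjusted p = 0.0774 in camera), without dim probe sets (adjusted p = 0.0609 in camera) and with the 3' to 5' covariate (adjusted p = 0.111 in camera). In fry, against no change, the adjusted p was 0.109. Adjusted over their lists alone, 1 gene rose in each of these 2 lists.

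In the 12 measured genes of 75 pooled from 5 lists of nuclear photosynthesis genes, 1 fell and 11 did not pass, 11 of the 12 differences were negative and the median was -0.23; adjusted over the pooled list alone, 5 fell. Their mean over the arrays was 0.27 lower in prors1-2 without overlap between the groups, with an exact permutation p of 0.1. The gene that fell was SBPASE, the Calvin cycle's sedoheptulose bisphosphatase, by 0.45 on the log2 scale, a call lost with each of the 6 arrays left out, with adjusted p values up to 0.137 in limma. The pooled list was made because the annotation named few members of each. It passed camera with an adjusted p of 0.00544, against 0.326 with an estimated correlation. Both values were adjusted over 36 lists, whereas those of the fixed lists were adjusted over 11. Among 8 tetrapyrrole genes, PORB, which reduces protochlorophyllide on the way to chlorophyll, fell by 1.04 on the log2 scale and 7 did not pass; adjusted over the list alone, 2 fell and 1 rose, and the camera adjusted p was 0.562. The cold-response gene COR47 fell by 0.89 with 4 other genes of its list not past the test, and adjusted over that list alone 2 fell and 1 rose. BCAT4, of glucosinolate synthesis, fell by 0.91 while the other measured gene of its list did not pass, and adjusted over the list alone 1 fell. The calls on COR47 and BCAT4 were lost with 4 and 5 of the 6 arrays left out, with adjusted p values up to 0.136 and 0.079 in limma. PDF1.2 was 1 of 3 measured jasmonate genes, of which 2 did not pass; adjusted over the list alone, 1 rose and 1 fell. Of 115 cytosolic ribosomal protein genes, 1 rose, 1 fell and 113 did not pass; adjusted over the list alone, 1 fell and 0 rose.

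**Figure D3:**
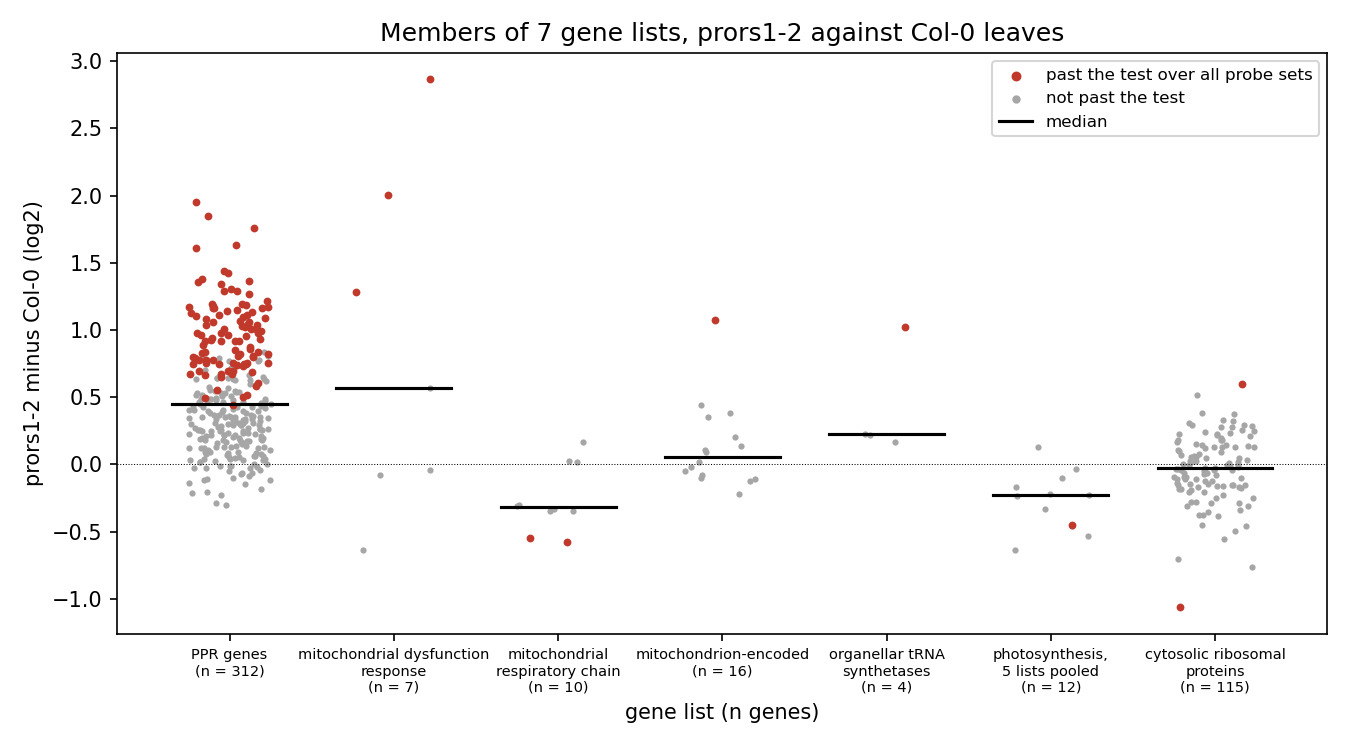
Each point is a gene of the list named on the horizontal axis, at its difference prors1-2 minus Col-0 (log2); red points passed an adjusted p under 0.05 and black bars are medians. The PPR genes, with 104 of 312 past the test and a median of 0.45, lie above 0 where the 115 cytosolic ribosomal protein genes centre on it; scaled to the poly(A) spikes 30 PPR genes were higher and 54 lower, the PPR median was -0.16 and the median of all genes -0.63.

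Another 20 lists had measured genes but none past the test over all probe sets. These lists were thinly measured, with 1 of 18 genes for salicylic acid, 3 of 17 for senescence and 2 of 21 for phase change, so they cannot be called unchanged. They were photorespiration, plastid ribosomal proteins, flavonoid synthesis, light harvesting, both photosystems, electron transport, carotenoids, plastid chaperones, antioxidant enzymes, proline, salicylic acid, starch, senescence, phase change, the evening clock, and markers of roots, meristems, stomata and trichomes. Their 52 genes, counted once per list, had 24 positive and 28 negative differences from -0.72 to 0.78, and adjusted over each list alone 4 rose and 6 fell. The markers of other organs and cell types thus gave 0 calls in limma over 8 measured genes, with 1 higher and 1 lower at an unadjusted p under 0.05.

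The control probe sets also differed between the groups. The poly(A) spikes, bacterial transcripts added before labelling, were at 6.26 ± 0.12 in Col-0 and 6.87 ± 0.24 in prors1-2 (log2, SD, n = 3 per group), without overlap, and the exact two-sided permutation p was 0.1. The hybridisation spikes, added after labelling, were at 10.43 ± 0.07 and 10.55 ± 0.29, with an exact permutation p of 0.8. The signal of the 3' probe set minus that of the 5' probe set of actin was 1.78 ± 0.44 in Col-0 and 2.87 ± 0.55 in prors1-2 without overlap, with an exact permutation p of 0.1. For GAPDH it was 0.48 ± 0.37 and 0.92 ± 0.30, and for ubiquitin 0.69 ± 0.21 and 0.97 ± 0.21, with an exact permutation p of 0.3 for each. With the mean of these 3 differences as a covariate, 0 probe sets passed the test in limma and 2380 had an unadjusted p under 0.05, against 4630 without it.

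**Figure D4:**
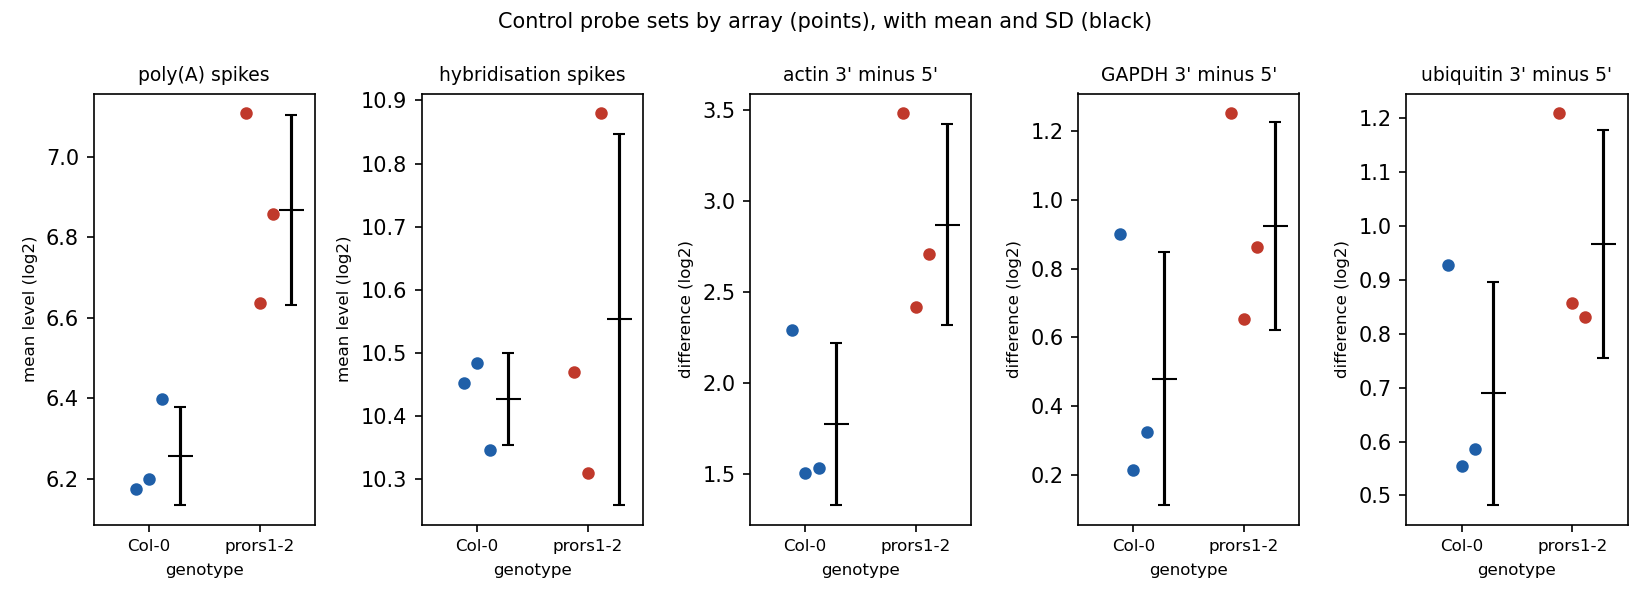
Points are the 6 arrays by genotype, at the mean level of the poly(A) and the hybridisation spikes and at the difference between the 3' and 5' probe sets of actin, GAPDH and ubiquitin (log2); black bars are the mean and SD, n = 3 per group. The poly(A) spikes and actin separate the groups, whereas the hybridisation spikes, GAPDH and ubiquitin overlap.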

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

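The tests of the control probe sets were chosen after their values were seen, except the share of each difference predicted by the 3' to 5' signal, which was fixed before it was computed.

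The poly(A) spike controls were 0.6112 higher (log2) in prors1-2, a signal in control probe sets outside the gene comparisons and above its level in the control genotype. Uneven hybridisation or array scaling stays open: after subtraction of the hybridisation spikes the difference was 0.4845, with overlap between the groups and an exact permutation p of 0.2. A smaller share of mRNA in the total RNA of prors1-2 and a larger volume of added spike would give the same 0.6112 and cannot be told apart, because each predicts the same values. The actin 3' minus 5' difference was also higher in prors1-2; the spikes' own 3' minus 5' difference was 0.1861 higher with overlap and an exact permutation p of 0.5, which leaves open whether leaf RNA had decayed before the spikes were added. Whether the 3' to 5' signal was the whole source of the called probe sets stays open. Its slope within the groups predicted a median share of 0.0528 of their differences, between -0.04 and 0.248 when single arrays were left out. This test cannot decide, because the called probe sets were picked for a small spread within the groups, which keeps such slopes small. The age and genotype of the plants also remain open and untested.

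For the counts of changed probe sets, the 10 splits of 6 arrays are too few for a share under 0.05. Only 1 split, the real one, gave as many as 1121 changed, 809 higher or 312 lower probe sets. The highest of the other splits gave 0 for each in limma. Every other split mixes both groups, so a difference between the groups enters its within-group spread and lowers its counts. The 0 calls therefore give no separate support. For the gene lists, 2 of the 10 splits gave at least the real number, with 4 lists past camera in the real split and 6 in the highest other split.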

How the results depend on the processing

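The alternatives were fixed before the data were examined except the scaling to poly(A) spikes, the 3' to 5' covariate, leaving out clpP and accD, the added lists and every result on PPR genes or on the division of plastid genes into housekeeping and photosynthesis. The numbers of changed, higher and lower probe sets stayed within 1.5 times the designed values without the trend, with a robust prior, without dim or shared probe sets, and after a second quantile normalization or median centring; array weights raised the lower ones to 496, and the cause was not tested. With 1 probe set per gene they were 693, 518 and 175 because fewer probe sets were tested, and at 2-fold or more 374, 277 and 97 by construction. Leaving out single arrays gave 337 to 888 changed, 245 to 668 higher and 92 to 220 lower, with fewer samples. Scaling to the poly(A) spikes lowered all differences by 0.61 and gave 16282 changed, 202 higher and 16080 lower; by construction it turned every positive difference under that size, among them the PPR median to -0.16, with 30 PPR genes higher and 54 lower, and 8 of 49 named genes, none past the test as deposited, of which LYC at -0.50 passed when scaled and 7 did not. With the 3' to 5' covariate 0 were changed, 0 higher and 0 lower in limma, with 2380 at an unadjusted p under 0.05; 53.5% of the covariate's variance lay between the groups and 3 residual degrees of freedom were left. With the replicate block the counts were 275, 204 and 71. The replicate numbers showed no pairing, as the deviations of same-numbered arrays correlated at -0.283, -0.01 and -0.28. Col-0 replicate 1 correlated at 0.31 with prors1-2 replicate 3, and Col-0 replicate 3 at 0.247 with prors1-2 replicate 1. The other differently numbered arrays lay between -0.0642 and 0.0679. Structure shared across the groups under other numbers thus stays open. Of the 4 lists past camera, 2 passed without dim probe sets, 2 with fry, 2 with the 3' to 5' covariate and 0 with an estimated correlation, and with the added lists 9 passed of 36; the cause was not tested. A robust prior was not run for lists, since camera has none. Of 29 named genes past the test, 18 passed under all 12 alternatives fixed for them other than the block, and 11 were lost when some array was left out, all with their direction kept. With the block 20 of the 29 passed, and with the 3' to 5' covariate 0 passed. Low signal over background limits the dim genes, whose differences GCRMA compresses.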

Other observations

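The test of a uniform change of plastid RNA and the bound of the gene-order test were chosen after the result was seen; the others were fixed before they were computed, on lists or splits chosen from the same data. Families of genes that share a symbol stem, added before the groups were compared, held further falls in prors1-2. Of 10 alpha-expansin genes (EXPA), 2 fell, EXPA4 and EXPA9, 0 rose and 8 did not pass, and 9 had negative differences with a median of -0.42; the camera adjusted p over 36 lists was 0.00128, against 0.272 with an estimated correlation. Of 19 genes with the stem GH, which joins GH9 cellulases and GH3 auxin-conjugating enzymes, 2 fell, GH9C2 by 0.69 and GH3.9 by 0.98 on the log2 scale, with an adjusted p of 0.00555 in camera, against 0.272 with an estimated correlation. Of 29 serine carboxypeptidase-like genes (SCPL), SCPL27 fell by 0.69 and 28 did not pass, with an adjusted p of 0.0244 in camera, against 0.272 with an estimated correlation. Of 11 genes with the stem PRA, 0 passed in limma and 4 were lower at an unadjusted p under 0.05, while 10 were negative with a median of -0.30 and an adjusted p of 0.00555 in camera, against 0.362 with an estimated correlation. The other 17 of 21 families did not pass. These members were named after their values were seen. Of the 11 further thylakoid genes, NDHS, likewise named after its values were seen, fell by 0.77 on the log2 scale with an adjusted p of 0.00869 in limma and 10 did not pass; they had a median of -0.13 and an adjusted p of 0.0514 in camera.

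The rise of PPR genes in prors1-2 was set against technical sources. A shift shared by genes of their level is argued against, since the central 99% of 10000 level-matched random lists had medians up to 0.00718 where the PPR median was 0.45, and with gene length matched too the bound was 0.0110. Gene length is not transcript length, which was not matched. Selection of the members seen beforehand is also argued against, as the median without them was 0.4321. The 3' to 5' signal as the whole source predicted a shift of 0.0532 and at most 0.186 with an array left out. With it as a covariate the median was 0.42 and 0 PPR genes passed in limma. The median SE rose from 0.16 to 0.24 and the residual degrees of freedom fell from 4 to 3. What ended the calls was not tested. Of the 10 splits, too few for a share under 0.05, 1 gave a PPR mean difference as large as the real 0.52. The highest other split gave 0.242. Every other split mixes both groups and so holds only part of a difference between them. The list was also written after rises in the real split were seen. This ranking was thus largely fixed in advance and gives no separate support. The genotype and the age of the plants, a change in total mRNA and correlated expression of these genes stay open.

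The plastid transcripts that moved both ways were weighed likewise. A single uniform change of plastid RNA or of its labelling would move all genes the same way, whereas 6 genes fell while 20 rose. With single arrays left out, 1 to 7 were lower and 8 to 13 higher. This check restates the pattern, so its outcome was fixed in advance and it gives no separate support. The gap between housekeeping and photosynthesis genes was 0.7799 after a straight line on level was removed. Its two-sided permutation p was 0.00023 over genes, which were read on the same arrays, so it does not measure the spread between samples. Removing the line could hardly move the gap, because the classes had close mean levels in Col-0, 9.47 and 9.69 (log2). A straight line also does not model compression, which shrinks differences of both signs, so compression by level stays open. The gap was 0.64 to 0.86 with single arrays left out and 0.70 with the 3' to 5' covariate, and 0.79 without clpP and accD. The genotype and the age of the plants and gene-specific differences in RNA processing or in poly(A) priming stay open, as none was tested.

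A passenger segment or another shared local source was tested by gene order. Adjacent measured genes were called in the same direction in 23 pairs, against a mean of 16.9 over 10000 random orders and a one-sided permutation p of 0.0841, which leaves the question open. Among the 40 measured genes nearest to the position of PRORS1, 0 were higher and 0 lower in limma at the adjusted threshold, and 1 was higher and 5 were lower at an unadjusted p under 0.05.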
